A study of Mus musculus with 8 samples.

How the data were processed

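Renal cortex RNA from 8 male mice was measured by RNA sequencing, 1 library per sample, in 4 db/db and 4 db/m samples. The labels number the samples 1 to 4 in each group and call them mice, so each sample was taken as 1 animal. db/db mice carry 2 mutated copies of the leptin receptor gene Lepr and become obese and diabetic, and db/m mice carry 1 and do not. The age of the mice is not given in the sources used here.

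Per the labels' protocols, messenger RNA was selected from total RNA with oligo(dT) beads, fragmented and copied into libraries in which dUTP marked the second cDNA strand. Per the submitters' processing notes, the tools used were cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR, on the mouse build GRCm38. Their order, options, annotation release, treatment of reads with several matches and use of strand are not given in the sources used here. The authors deposited 1 table of counts per gene, whole numbers that were not normalized, with 55401 Ensembl gene identifiers and 1 column for each of the 8 samples. Of these identifiers, 55141 matched a gene symbol in the name table used here. Columns were tied to samples by the sample descriptions. Coordinates are those of GENCODE M21 on GRCm38, counted from 1.

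Totals ran from 46247206 to 72215318 counts per library. Genes of the mitochondrial genome took 22.8% to 61.7% of them. A cluster of 7 pseudogenes on chromosome 1 took another 6.76% to 15.8%. A blastn search matched these 7 pseudogenes to mitochondrial genes at 99.7% to 100% identity over 99.8% of their length, so reads from either copy cannot be assigned by sequence. One ribosomal RNA gene, CT010467.1, took 0.0961% to 21.5%. After these and Lars2 were set aside, 10048180 to 50556576 counts per library remained for all other genes. The 95% Wilson intervals of the mitochondrial shares were at most 0.029 percentage points wide. Such intervals, and the floor of 3 counts used for a count of 0, cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

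The tests, samples, gene lists and rule for named genes were fixed before the data were examined. The counts as deposited were filtered with filterByExpr, which kept 18725 genes, and scaled by TMM. Groups were compared with edgeR's quasi-likelihood F test in R 4.3.3 (edgeR 4.0.16, intercept and group, all 8 libraries). P-values were adjusted by Benjamini-Hochberg and called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Expression is given as CPM, counts scaled to library size after TMM, as mean ± SD over 4 libraries per group unless stated. log2 CPM for lists and principal components used a prior count of 2. Principal components were computed on the 500 most variable genes.

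The 39 gene lists covered cell types of the kidney and of blood and fat, metabolic and stress pathways, sex-biased kidney genes, and genes that respond to tissue handling. The 38 lists with at least 5 tested members were tested with camera (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. The neutrophil list had 4 tested members and was not tested. Beside each call stand the adjusted p with a correlation estimated per list and the number of members past the threshold when p-values were adjusted over the list alone. A list's score in a library is the mean log2 CPM of its tested members minus the mean of the db/m libraries. List scores and library measures were compared with exact two-sided permutation tests over all 70 labelings, for which 0.029 is the smallest possible p.

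Named genes were Lepr first; then up to 12 genes in each direction past the threshold, with a symbol that is not a predicted or clone name, a mean of at least 1 CPM in the higher group and groups that did not overlap; then up to 4 members with the smallest p of each list that was called or had at least 2 members past the threshold; and 9 kidney genes whatever their test gave, namely Slc5a2, Havcr1, Lcn2, Nphs1, Col4a1, Fn1, Ren1, Pck1 and Umod. Gm6614, Cyp2d37-ps, Gm853 and 3110045C21Rik fell outside the rule, as did members of other lists and sex-linked genes. These were chosen after their values were seen. Some list members that the rule or these choices would name are not reported here.

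The procedure was also tested, after a first run on the deposited counts, on simulated counts with the means and library sizes of these samples. Of 67 genes changed 2-fold 0 were called, of 67 changed 4-fold 31 (46.3%) and of 66 changed 8-fold 39 (59.1%), with 1 false call in 71 calls among 17981 genes. The one shifted list was called, and no other of the 38 lists. Genes were drawn independently of each other, so this could not show false list calls that arise from correlated genes. All libraries were drawn from a common mean profile. False gene calls that arise from differences in makeup between libraries could therefore not show either. In the deposited counts the estimated correlation within a list ran from −0.08 to 0.99.

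Alternatives set before the data were examined were the DESeq2 size factors, library size alone and upper quartile in place of TMM, no filter or a stricter one, DESeq2 1.42.0 and limma-voom as other tools, a block for the replicate number, a minimum fold, only rows with a symbol, an estimated correlation or fry for lists, and leaving out each library. The planned removal of StringTie's unnamed loci became the removal of 260 identifiers without a symbol, since the table held no such loci. Added after seeing the data were the mitochondrial share, the medulla marker score or Slc14a2 as a covariate, the relation of the latter 2 to the S1-S2 score, removal of mitochondrial genes, the 7 pseudogenes, CT010467.1 and Lars2, removal of 3 libraries (db/db 2 and db/m 2, with mitochondrial shares over 60%, and db/db 3, with CT010467.1 over 20%), a robust fit, and separate fits of the 4 libraries with a mitochondrial share under 40% (db/db 1, db/db 4, db/m 3, db/m 4) and of the 4 over it.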

Results

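The series asked which genes differ in the renal cortex between diabetic db/db and non-diabetic db/m mice. Each group had 4 male mice. db/db mice lack the long signalling form of the leptin receptor and serve as a model of type 2 diabetes. Total counts were 60434994, 62492251, 46247206 and 72215318 for db/db 1 to 4 and 56143911, 63487580, 71063462 and 61831284 for db/m 1 to 4.

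The libraries differed in makeup within both groups. Mitochondrial genes took 34.6%, 61.7%, 42.9% and 22.8% of counts in db/db 1 to 4 and 46.3%, 60.3%, 24% and 26.9% in db/m 1 to 4. The group means were 40.5% ± 16.4 and 39.4% ± 17.1 (SD, n = 4), with an exact permutation p of 0.943. In db/db 3 the ribosomal RNA gene CT010467.1 took 21.5% of counts, with a 95% Wilson interval of 21.53% to 21.56%, and Lars2, the mitochondrial leucyl-tRNA synthetase gene, took 3.01%. Counts left for all other genes were 33436551, 13596263, 10048180 and 50556576 in db/db 1 to 4 and 23228478, 15400642, 48995662 and 38993243 in db/m 1 to 4.

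**Figure D1:**
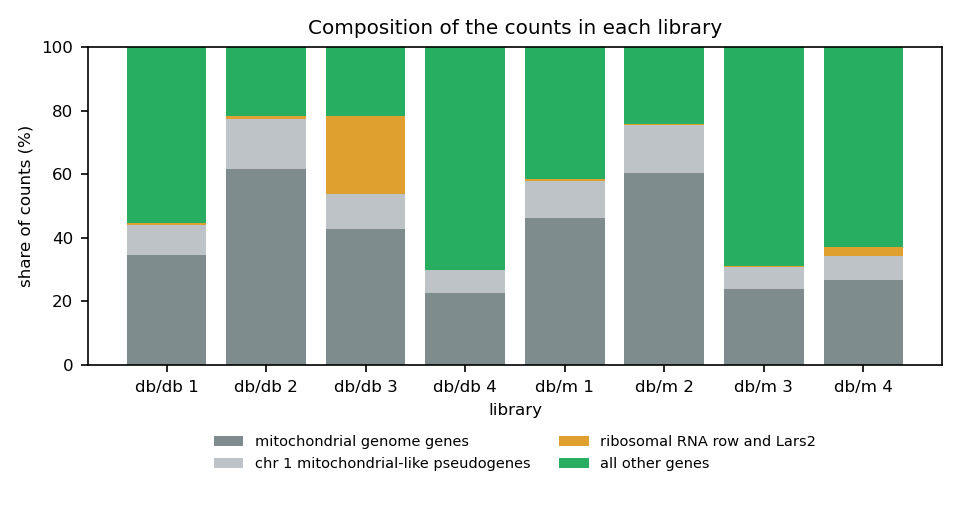
Share of counts (%, vertical axis) taken by 4 classes of genes in each of the 8 libraries (horizontal axis). Mitochondrial genes ran from 22.8% in db/db 4 to 61.7% in db/db 2, and the ribosomal RNA gene with Lars2 stands out in db/db 3.

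Lepr, the gene that carries the db mutation (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352, plus strand), was at 13.1, 6.3, 5.77 and 3.12 CPM in db/db 1 to 4 and at 11.1, 8.83, 7.84 and 1.77 CPM in db/m 1 to 4. The group means were 7.06 ± 4.24 and 7.38 ± 3.99 CPM (SD, n = 4). Its log2 fold change was −0.06 (SE 0.55, edgeR adjusted p = 0.98), and its sign turned under library-size scaling (0.12). The count per gene sums all transcript forms and so does not check the genotype. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to between 74.4 and 111 CPM in the 8 libraries, and Xist, which silences the second X chromosome in females, was at 2.18 CPM or less.

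On the first principal component (36.2% of variance) db/db 4 lay beside db/m 3 and db/m 4, at 35.2 against 35.3 and 39.1. The other db/db libraries lay between −47.3 and −22.3. On the second component db/db 4 lay far from those 2 db/m libraries, at −50.2 against 7.95 and 24.7. There db/db 1 to 3 lay at −24.3, −8.33 and 12.1, and db/m 1 and db/m 2 at 5.03 and 33. The groups were not separated on the first component (exact permutation p = 0.143) or on the second component (22.2% of variance, exact permutation p = 0.0857), although the second gave an exact permutation p of 0.0286 with a prior count of 0.5.

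**Figure D2:**
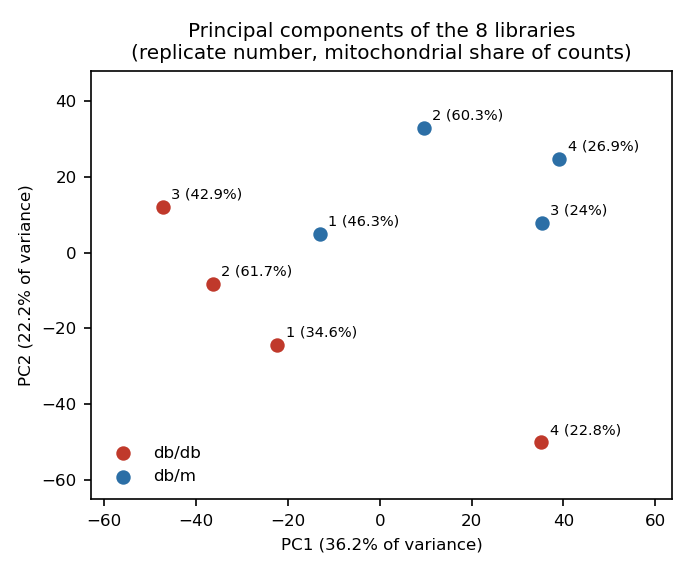
First 2 principal components of log2 CPM over 500 genes (axes, in component units), 1 point per library, coloured by group and marked with replicate number and mitochondrial share. On the horizontal axis db/db 4 (35.2) sits with db/m 3 (35.3) and db/m 4 (39.1), away from the other db/db libraries. On the vertical axis db/db 4 (−50.2) lies far from db/m 3 (7.95) and db/m 4 (24.7).

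In db/db cortex 10 genes fell and 3 rose. Slc22a7, an organic anion transporter of the proximal tubule, fell from 121 ± 31.2 to 2.51 ± 2.15 CPM, a log2 fold change of −5.60 (SE 0.72, edgeR adjusted p = 0.045). Acsm3, a mitochondrial acyl-CoA synthetase, fell from 167 ± 109 to 3.87 ± 2.71 CPM (−5.44, SE 0.74, adjusted p = 0.045). Slc22a26, another member of the organic anion transporter family, fell from 14.2 ± 4.89 to 0.405 ± 0.218 CPM (−5.18, SE 0.49, adjusted p = 0.02). Cyp4a12a, a fatty acid hydroxylase of male mouse kidney, fell from 106 ± 49.6 to 8.46 ± 4.57 CPM (−3.65, SE 0.50, adjusted p = 0.045).

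Alox15, an arachidonate lipoxygenase, had a log2 fold change of −3.68, Kif20b, a kinesin of cell division, −3.03, Ugt2b5, a glucuronosyltransferase, −2.41 and the villin-like gene Vill −1.57. Their adjusted p-values ran from 0.025 for Ugt2b5 to 0.048 for Vill. The genes outside the naming rule were Gm853 (−3.16) and the antisense RNA gene 3110045C21Rik (−2.58), both lower, and Gm6614 (3.44) and the pseudogene Cyp2d37-ps (4.65), both higher. Slc22a7 lies on chromosome 17 (46432183 to 46438457), Acsm3 on chromosome 7 (119760923 to 119787513), Slc22a26 on chromosome 19 (7781041 to 7802667) and Cyp4a12a on chromosome 4 (115299046 to 115332815). Cyp4a12a, Ugt2b5, Slc22a26, Gm6614 and Cyp2d37-ps belong to families of close paralogs, and the exons of Acsm3 and 3110045C21Rik overlap Eri2 and Ddr2 on the other strand, so their counts are uncertain to the extent that reads were divided between copies or strands.

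Ugt1a2, a glucuronosyltransferase gene (ENSMUSG00000090171, chromosome 1, 88200601 to 88218997, plus strand), was at 102, 54.1, 31.3 and 256 CPM in db/db 1 to 4 and at 0 counts in all 4 db/m libraries. The db/db mean of 111 CPM was at least 1493-fold above a floor of 3 counts per library (edgeR adjusted p = 0.0354). This floor covers counting error, not the division of reads among genes that share exons. Ugt1a2 shares exons with 8 other Ugt1a genes, whose summed expression without Ugt1a2 was 28.4, 25.6, 46.5 and 204 CPM in db/db 1 to 4 and 55.9, 45.3, 304 and 246 CPM in db/m 1 to 4. The sum over all 9 Ugt1a genes was 187 ± 184 CPM in db/db and 163 ± 132 CPM in db/m (SD, n = 4, exact permutation p = 0.83), so no group difference was detected for the family.

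**Figure D3:**
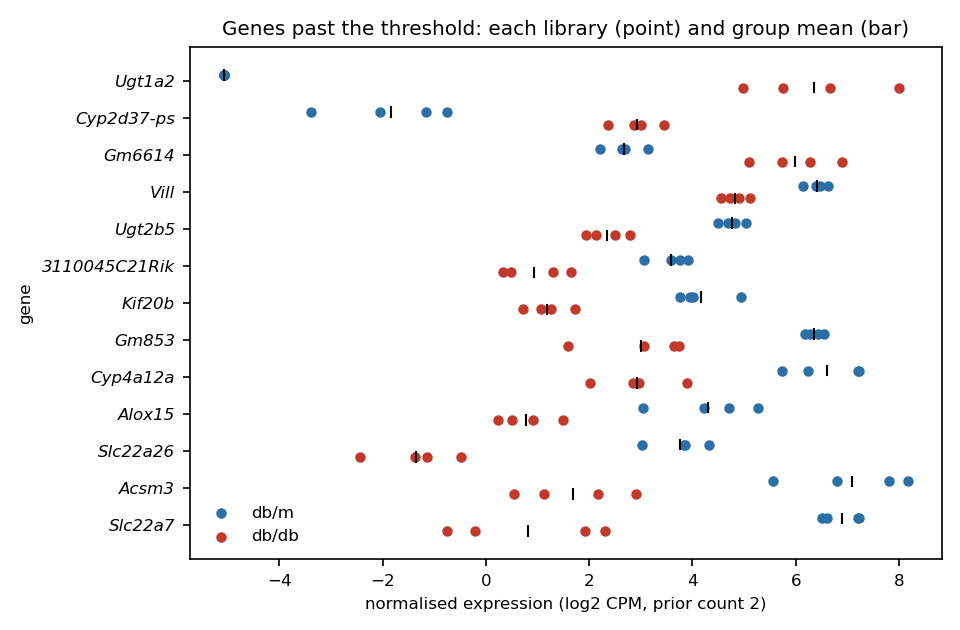
Normalised expression (log2 CPM with a prior count of 2, horizontal axis) of the 13 genes past the threshold, 1 point per library and a bar at each group mean. The groups do not overlap for any of the 13 genes, and the 4 db/m libraries coincide for Ugt1a2 because each had 0 counts.

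Of the 18725 genes tested with edgeR's quasi-likelihood test, 2096 had an unadjusted p under 0.05, of which 1128 were higher and 968 lower, against 936 expected by chance. The groups did not overlap for 1169 genes (6.24%), where chance gives 2.86%. The 13 calls depended on single libraries: genes higher and lower numbered 1 and 3 without db/db 1, 0 and 0 without db/db 2, 0 and 1 without db/db 3, 43 and 138 without db/db 4, 2 and 7 without db/m 1, 0 and 0 without db/m 2, 1 and 0 without db/m 3, and 0 and 0 without db/m 4. Unadjusted p-values under 0.05 numbered 1656 without db/db 2, 1573 without db/db 3, 1888 without db/m 2, 1751 without db/m 3 and 1297 without db/m 4. DESeq2 called 155 genes higher and 263 lower, limma-voom 2 and 15, and edgeR with a block for the replicate number 39 and 65. With db/db 2, db/db 3 and db/m 2 left out edgeR called 0 and 0 (998 with an unadjusted p under 0.05). The 4 libraries with mitochondrial shares under 40% gave 0 higher and 0 lower (1331 with an unadjusted p under 0.05, other tools not run) and the 4 over 40% gave 11 and 15. The 13 genes kept their direction in each of these fits. With 1 library left out, their largest edgeR adjusted p was 0.23, without db/db 3. They were chosen on these same libraries, so this is not independent support.

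Genes known to be expressed more in male than in female mouse kidney were lower in db/db males. Of 12 male-biased genes 11 had a log2 fold change below 0, with a median of −2.24. One of them, Acsm3, passed over all genes tested and 10 passed when adjusted over the list alone. Kap, the abundant kidney androgen-regulated protein gene, was at 1670 ± 1680 CPM in db/db and 26700 ± 13100 CPM in db/m (log2 fold change −4.00, SE 0.89, edgeR adjusted p = 0.169). Slco1a1, an organic anion transporter, was at 2.69 ± 3.04 and 140 ± 106 CPM (−5.73, SE 1.02, adjusted p = 0.0911). Cyp7b1, an oxysterol hydroxylase, had −3.39 (SE 0.70, adjusted p = 0.141).

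The male-biased list was past the competitive threshold (limma camera adjusted p = 2.62e-09; adjusted p = 0.861 with an estimated correlation). It stayed past the preset-correlation threshold without each of the 8 libraries, with 7 to 11 members lower when adjusted over the list alone. Its score per library had an exact permutation p of 0.0286 (adjusted 0.557). Without db/db 4 its median was −3.44. Without db/db 2, db/db 3 and db/m 2 its median was −2.09 (camera adjusted p = 1.71e-07) and 5 members passed when adjusted over the list alone. Its median was −1.34 with Slc14a2 as a covariate (camera adjusted p = 1.99e-06), −2.53 in the libraries with mitochondrial shares under 40% and −1.68 in those over 40%.

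Female-biased kidney genes went mostly the other way. Of 7 tested members 6 had a log2 fold change above 0, and the median was 1.23 (camera adjusted p = 0.0376; adjusted p = 0.861 with an estimated correlation). None passed over all genes tested, and adjusted over the list alone 2 were higher, Cyp4a14 (3.72, SE 0.77) and the prolactin receptor gene Prlr (1.84, SE 0.51), and 1 lower, Cyp2a4 (−2.65, SE 0.59), a steroid hydroxylase with a near-identical paralog. Slc7a12, an amino acid transporter gene, had 1.94 (SE 0.86, edgeR adjusted p = 0.442). Without db/db 1 the median was 1.85. The list's call was lost without db/db 2 (camera adjusted p = 0.0904), db/db 4 (0.257) or db/m 1 (0.068), and without the 3 libraries together (0.052). The median was 1.72 in libraries with mitochondrial shares under 40% (adjusted p = 0.0912) and 1.70 in those over it.

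**Figure D4:**
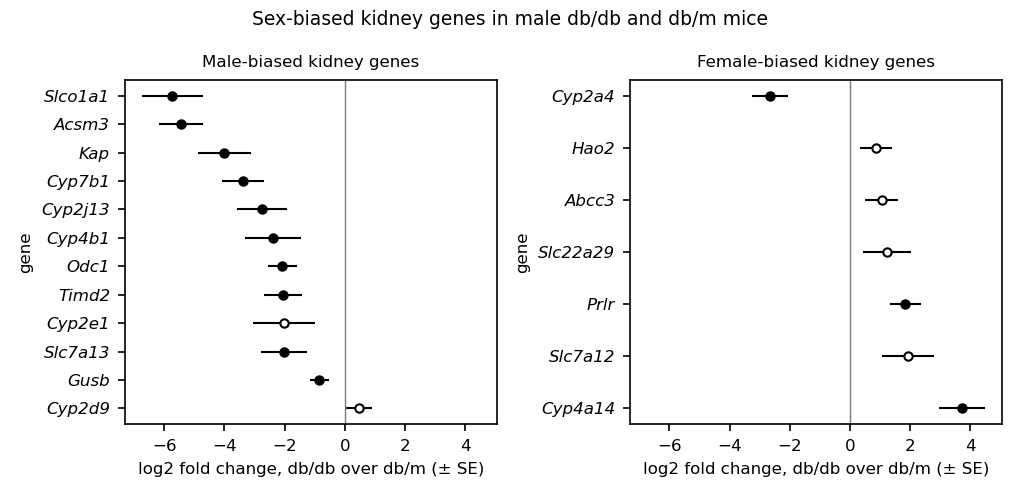
Log2 fold change of db/db over db/m (horizontal axis, bars ± 1 SE, 4 libraries per group) for each tested gene of the male-biased and female-biased kidney lists. Filled points passed when adjusted over the list alone, 10 of 12 on the left and 3 of 7 on the right.

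Transporters of the proximal tubule, the segment that reclaims most of the filtrate, were lower in 3 of the 4 db/db libraries. Of 15 genes of the early (S1 and S2) segments 14 had a log2 fold change below 0, with a median of −0.67 (camera adjusted p = 0.000124; adjusted p = 0.861 with an estimated correlation). None passed over all genes (2 had an unadjusted edgeR p under 0.05) or adjusted over the list alone. The urate transporter gene Slc22a12 was at 190 ± 108 CPM in db/db and 586 ± 168 CPM in db/m (−1.63, SE 0.43, adjusted p = 0.246). The organic anion transporter genes Slc22a6 and Slc22a8 had −1.50 (SE 0.48) and −0.95 (SE 0.48), the endocytic receptor gene Lrp2 −0.93 (SE 0.52) and the glucose transporter gene Slc5a2 −1.01 (SE 0.70), with adjusted p-values of 0.334, 0.497, 0.533 and 0.614. The list's score was −1.45, −1.42 and −1.71 in db/db 1 to 3 and 0.57 in db/db 4, against −0.61, −0.46, 0.52 and 0.55 in db/m 1 to 4 (exact permutation p = 0.2, adjusted 0.557). The score of medulla and urothelium markers ran against it, at 1.16, 0.70, 1.10 and −0.81 in db/db 1 to 4 and 3.41, 0.51, −0.10 and −3.82 in db/m 1 to 4 (Pearson r = −0.60, exact permutation p = 0.1; Spearman rho = −0.81, exact permutation p = 0.022; r = −0.93 without db/m 1 and db/m 4, −0.98 within db/db and −0.81 within db/m). Of its 8 genes 7 mark urothelium, and Slc14a2, a urea transporter gene of the medulla, was at a log2 CPM of 8.4, 7.1, 6.6 and 4.8 in db/db 1 to 4 and 6.4, 4.8, 3.7 and −1.2 in db/m 1 to 4 (log2 fold change 2.26, SE 1.16, edgeR adjusted p = 0.499; r = −0.77 with the S1-S2 score, exact permutation p = 0.0064). The S1-S2 median was −0.68 (camera adjusted p = 0.000194) with the marker score as a covariate and 0.05 (0.269) with Slc14a2.

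Without db/db 4 the median of these early-segment genes was −1.48 and 14 of them passed when adjusted over the list alone, and without db/m 3 the median was −0.44. With the replicate block it was −0.98 and 6 passed. Without the 3 doubted libraries it was −0.32, and the camera call was lost (adjusted p = 0.052). It was −0.70 in libraries with mitochondrial shares under 40% and −0.78 in those over 40%. Genes of the late (S3) segment had a median of −1.58 (camera adjusted p = 5.64e-06; adjusted p = 0.861 with an estimated correlation), and 1 of 10, Slc22a7, was lower over all genes and 6 adjusted over the list alone. Besides Slc22a7 and Cyp7b1 these included the aminoacylase gene Acy3 (−2.60, SE 0.67) and the transporter gene Slco1a6 (−1.92, SE 0.50), with edgeR adjusted p-values of 0.238 and 0.243. The S3 call stood without each of the 8 libraries, with 5 to 8 members lower adjusted over the list alone, and Cyp7b1 and Slc7a13 are also in the male-biased list. The S3 median was −1.86 in libraries with mitochondrial shares under 40% and −1.19 in those over it. With Slc14a2 as a covariate it was −0.93 and the call stood (camera adjusted p = 0.00121), but only 2 members were lower adjusted over the list alone.

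Genes of energy metabolism in mitochondria were lower by camera, but their scores per library did not separate the groups (exact permutation p = 0.2 and 0.486, adjusted 0.557 and 0.847). Of 18 fatty acid oxidation genes 15 had a log2 fold change below 0 (median −0.49, camera adjusted p = 0.0228), and of 20 nuclear genes of oxidative phosphorylation all 20 did (median −0.35, camera adjusted p = 0.0376). Each had an adjusted p = 0.907 with an estimated correlation, and no member of either passed over all genes or adjusted over the list alone (0 had an unadjusted edgeR p under 0.05). Acadm, an enzyme of the first step of fatty acid oxidation, had −0.91 (SE 0.42), Decr1 and Ehhadh −0.83 (SE 0.40) and −1.47 (SE 0.79), and Sdhb, Sdhc and Ndufv1, subunits of respiratory complexes, had −0.78, −0.70 and −0.56. The fatty acid oxidation call was lost without db/db 1 (camera adjusted p = 0.181), db/db 2 (0.0904), db/db 3 (0.115), db/m 3 (0.456) or db/m 4 (0.0839). The oxidative phosphorylation call was lost without the same libraries (0.187, 0.145, 0.338, 0.532 and 0.282 in that order), with medians of −0.21, −0.20, −0.16, −0.06 and −0.19. Its median was −0.92 without db/db 4 (camera adjusted p = 0.000115), −0.54 without db/m 1 and −0.57 without db/m 2. The fatty acid oxidation median was −0.77 without db/db 4, with 5 members lower adjusted over the list alone, and −0.17 without db/m 3. Without the 3 doubted libraries the camera adjusted p-values were 0.144 and 0.231, and with Slc14a2 as a covariate the medians were −0.06 and 0.28 and both calls were lost (0.757 and 0.123).

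The score of the oxidative phosphorylation genes ran against the mitochondrial share of the library (Pearson r = −0.82, exact permutation p = 0.027, adjusted 0.081 over 3 relations; Spearman rho = −0.67, exact permutation p = 0.083), and r was −0.90 without db/db 2 and db/m 2. In libraries with mitochondrial shares under 40% the medians of the 2 lists were −0.71 and −0.49 (camera adjusted p = 0.00228 and 0.00277), and in those over 40% −0.24 and −0.19 (0.356 and 0.386). The 13 genes of the mitochondrial genome had a median of 0.10 (camera adjusted p = 0.912).

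Cholesterol synthesis genes were lower in db/db, 18 of 20 with a log2 fold change below 0 and a median of −0.35 (camera adjusted p = 0.00617; adjusted p = 0.861 with an estimated correlation). None passed over all genes (5 had an unadjusted edgeR p under 0.05), and 2 did adjusted over the list alone, the sterol demethylase gene Cyp51 (13.1 ± 5.58 against 68.9 ± 38.7 CPM, −2.39, SE 0.46) and Idi1 (−1.89, SE 0.45). Mvd and Hmgcs1 had −1.35 (SE 0.45) and −0.86 (SE 0.29). Members lower adjusted over the list alone numbered 1 without db/db 2, db/db 3 or db/m 4, 4 without db/db 4 or db/m 2 and 3 without db/m 3. The call was lost without db/db 2 (camera adjusted p = 0.0858) or db/m 3 (0.0586), and in the libraries with mitochondrial shares over 40% (0.246, median −0.17, against −0.58 in those under it). It was also lost with Slc14a2 as a covariate (camera adjusted p = 0.123, median −0.17), where 0 members passed adjusted over the list alone.

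Several lists of blood and immune cell genes were lower. Macrophage and monocyte genes, 8 of 13 below 0, had a median of −0.57 and lymphocyte genes −0.85 (camera adjusted p = 0.0167 for both), the NADPH oxidase genes of phagocytes and other cells −0.66 and hemoglobin and other erythroid genes −1.42 (0.0219 for both), each with an adjusted p = 0.861 with an estimated correlation. Antigen presentation genes had −0.25 (camera adjusted p = 0.0191; adjusted p = 0.907 with an estimated correlation). No member passed over all genes tested, and adjusted over the list alone C1qa (4.53 ± 1.5 against 10.4 ± 2.92 CPM, −1.19, SE 0.31) was the only one lower. That count was 0 for macrophages without db/db 2, db/db 3, db/m 1, db/m 3 or db/m 4, 2 without db/db 4 and 3 without db/m 2; it was 2 for lymphocytes without db/db 1, 4 for erythroid genes without db/db 4 or db/m 2 and 2 for NADPH oxidase without db/db 4. C1qb had −1.11, Ccr2 −1.17, Fcgr1 −1.38, Cd68 0.03, Adgre1 0.08 and Lyz2 0.53; Igkc −1.80, Ighm −0.85, Cd4 −1.61 and Cd79b 1.46; Ncf4 −0.84, Cybb −0.59 and Cyba −1.29. The class II genes H2-Aa and H2-Eb1 had −1.36 and −1.33, Cd74 −0.78 and H2-D1 −0.49, and Hba-a1, Hba-a2, Hbb-bt and Hbb-bs, which are near copies of each other in pairs, had −1.42, −1.45, −1.51 and −1.30. The 4 tested neutrophil genes had a median of 0.25 and were not called.

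Each of these 5 calls was lost without some single libraries. The NADPH oxidase score nonetheless separated the groups, at −1.28 to −0.54 in db/db and −0.21 to 0.14 in db/m (exact permutation p = 0.0286, adjusted 0.557). Without db/db 2 the camera adjusted p-values were 0.122 for macrophages, 0.0858 for lymphocytes, 0.0904 for NADPH oxidase, 0.0968 for erythroid genes and 0.143 for antigen presentation, and without db/m 1 they were 0.0884, 0.0884, 0.068, 0.0806 and 0.135. Without db/db 4 macrophages had 0.0545, lymphocytes 0.132 and antigen presentation 0.135, without db/db 1 erythroid genes had 0.0523 and antigen presentation 0.0623, and without db/m 3 erythroid genes had 0.108. The macrophage median was −0.37 without db/m 1. The antigen presentation score was 0.78 in db/db 3 against −0.94, −1.63 and −0.93 in db/db 1, 2 and 4, and the median was −1.14 without db/db 3 (camera adjusted p = 1.84e-08, 6 members lower adjusted over the list alone), −0.10 without db/db 2, −0.13 without db/db 4 and −0.11 without db/m 1. With the replicate block it was −0.57, with 2 members lower adjusted over the list alone, and 3 erythroid and 2 macrophage genes were lower. Without the 3 doubted libraries the antigen presentation median was −1.19 (camera adjusted p = 1.1e-09), while macrophages (0.052) and NADPH oxidase (0.125) lost the call. In libraries with mitochondrial shares under 40% and over 40% the medians were −0.38 and −0.72 for macrophages, −0.67 and −1.29 for lymphocytes, −0.42 and −0.94 for NADPH oxidase, −1.33 and −1.50 for erythroid genes and −0.89 and 0.01 for antigen presentation. Calls lost under 40% were those of macrophages (camera adjusted p = 0.335), lymphocytes (0.275) and NADPH oxidase (0.234). Those lost over 40% were erythroid genes (0.28) and antigen presentation (0.559). With Slc14a2 as a covariate the erythroid call was lost (camera adjusted p = 0.17) and the other calls of this group stood.

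Immediate early genes, which respond within minutes to stimulation and tissue handling, were higher in db/db, 12 of 15 above 0 with a median of 0.42 (camera adjusted p = 0.0219; adjusted p = 0.861 with an estimated correlation). None passed over all genes or adjusted over the list alone (2 had an unadjusted edgeR p under 0.05). Btg2 had 1.00 (SE 0.40), Klf6 0.58 (SE 0.25), Fos 0.94 (SE 0.50) and Egr1 1.23 (SE 0.70). The call was lost without db/db 2 (camera adjusted p = 0.0904), db/m 1 (0.0884), db/m 4 (0.163) or the 3 doubted libraries (0.052). The median was 0.24 without db/db 2 or db/m 4 and 0.71 without db/m 3 (camera adjusted p = 4.25e-05, 2 members higher adjusted over the list alone). It was 0.12 in libraries with mitochondrial shares under 40%, where the call was lost (camera adjusted p = 0.234), and 0.50 in those over it (0.00221). With Slc14a2 as a covariate the median was 0.14 and the call was lost (camera adjusted p = 0.235).

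**Figure D5:**
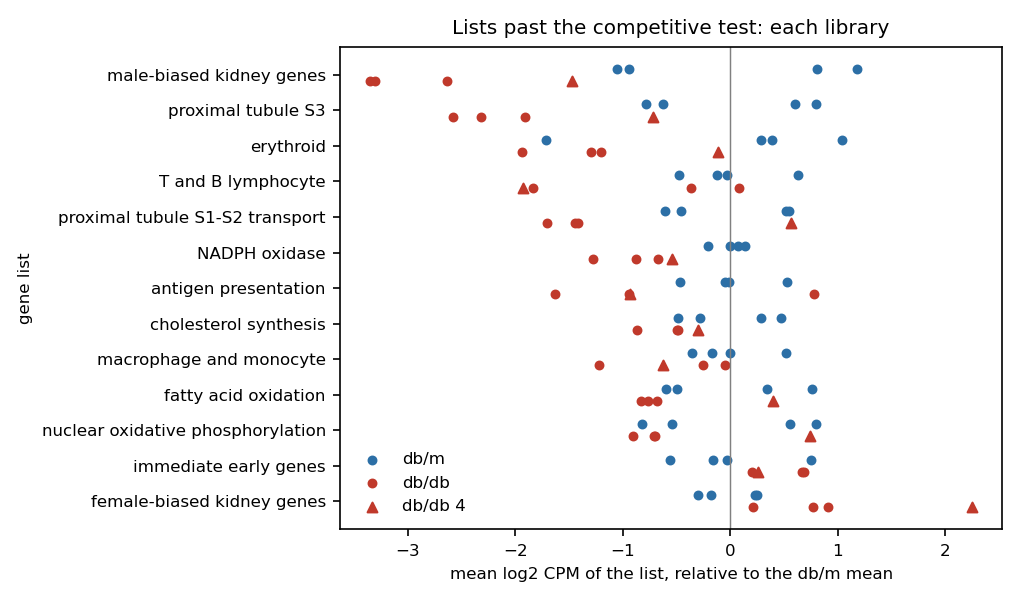
Mean log2 CPM of each called list relative to the db/m mean (horizontal axis), 1 point per library, with db/db 4 as a triangle. For the proximal tubule S1-S2 list db/db 4 (0.57) lies above all 4 db/m libraries and the other db/db libraries lie between −1.71 and −1.42. For the male-biased list (−3.35 to −1.47) and the NADPH oxidase list (−1.28 to −0.54) all 4 db/db libraries lie below all db/m libraries. The exact permutation p was 0.2 for S1-S2 and 0.0286 for each of the other 2, and 0.557 after adjustment for each of the 3.

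Of the 38 lists tested by camera 13 were called, 11 lower and 2 higher. With an estimated correlation 0 were called, and 1, NADPH oxidase, had an unadjusted p under 0.05 (camera p = 0.0287). The limma test fry, in its directional form, called 0, with the smallest adjusted p for NADPH oxidase (0.0719). Its mixed form, which takes members that change in either direction, was not used for calls. The smallest unadjusted p-values of mixed fry were 1.63e-06 for female-biased genes, 0.000799 for S3, 0.000808 for injury markers and 0.00141 for male-biased genes. Genes of the kidney filter and of scarring gave no call. Nphs1, the nephrin gene of podocytes, had a log2 fold change of −0.18 (SE 0.28), and the podocyte list had a median of 0.00 (camera adjusted p = 0.912). Col4a1 had 0.08 (SE 0.31) and Fn1, the fibronectin gene, 0.15 (SE 0.37), and the sign of Nphs1 and Col4a1 turned without some single libraries. Of 25 extracellular matrix genes 16 were above 0 and 9 below, with a median of 0.15 (camera adjusted p = 0.517), and without db/db 4 the median was 0.39 and the list was called (0.0444). Ren1, the renin gene, had −0.09 (SE 0.81), turning to 0.13 under library-size scaling. The gluconeogenic gene Pck1 had −0.68 (SE 0.75) and Umod, the uromodulin gene of the thick ascending limb, −1.30 (SE 0.51, adjusted p = 0.401).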

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

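Of the tests in this part only the counts over other splits of the libraries were set before their results were seen. The tests of the mitochondrial share, of medulla tissue, of the removal of 3 libraries, of a wrong label of db/db 4 and its control on held-out db/m libraries, of sex-linked genes, of the proximal tubule share, of androgen signalling and of the Ugt1a family were chosen after seeing the data. Single libraries stood far from the other 3 of their group in 15 of 181 values checked, where chance gives about 1 in 20, or 9. The values were not independent, since some list scores hold genes that were also checked, so 15 against 9 is not a test. Of the 15, db/db 4 accounted for 10.

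In db/db 3 CT010467.1 took 21.5% of counts, against 0.655% or less in the other db/db libraries, and Lars2 took 3.01%, against 0.0982% or less. In db/db 4 log2 CPM was 8.37 for Slc22a6, 5.66 for Slco1a6, 6.44 for Decr1, 6.99 for Ehhadh, 7.43 for Sdhc, 7.68 for Ndufv1 and 11.2 for Pck1, where the nearest other db/db library was at 6.74, 4.11, 5.25, 4.61, 5.7, 6.31 and 8.84. The scores of the same library were 0.57 for the proximal tubule S1-S2 list, 0.4 for fatty acid oxidation and 0.74 for oxidative phosphorylation, and the nearest others were at −1.42, −0.68 and −0.7. Ccr2 was at a log2 CPM of 1.31 in db/db 1, Cyp4a14 at 3.57 in db/m 3 and Col4a1 at 7.95 in db/m 2, and the nearest libraries of the same group were at 0.1, 1.85 and 7.02.

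Chance could not be excluded for the counts of genes and lists. Of the 35 splits of the 8 libraries into 4 and 4, the real one included, 4 gave at least 3 genes higher and 4 gave at least 10 lower, with 630 in one direction as the highest of the other splits. For lists 12 of 35 splits gave at least 13, and the highest other gave 23. The split of db/db 1, db/db 4, db/m 3 and db/m 4 from the rest, which parts mitochondrial shares under and over 40%, gave 843 genes. It holds 2 libraries of each genotype on each side, so its count points to a structure of the samples other than genotype. The split of db/db 1, 2 and 3 with db/m 2 from the rest gave 694; it moves only db/db 4 and db/m 2 across, and the genotypes without db/db 4 gave 181. Within the libraries under 40% edgeR called 0 genes (1331 with an unadjusted p under 0.05), and within those over 40% it called 11 higher and 15 lower.

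Proximal tubule S1-S2 and fatty acid oxidation scores were lower in db/db 1 to 3 than in each db/m library and in db/db 4 near those of db/m 3 and db/m 4. The oxidative phosphorylation score was −0.71, −0.70, −0.91 and 0.74 in db/db 1 to 4 and −0.54, −0.82, 0.80 and 0.56 in db/m 1 to 4. The mitochondrial share as a covariate left the median of the proximal tubule S1-S2 list at −0.90 (−0.67 without it) and past the threshold. The mean share was alike in db/db and db/m (40.5% and 39.4%, exact permutation p = 0.943). A covariate so balanced could hardly remove a group difference, so this fit is no separate evidence on that share as a cause. For fatty acid oxidation the median went from −0.49 to −0.38 and for oxidative phosphorylation from −0.35 to −0.28, too near the bound set for the test to decide. Both calls stood with this covariate, to which the same limit applies. Medulla tissue in the samples may be a cause and stays open. With the score of the medulla and urothelium list as a covariate the medians were −0.68 for S1-S2, −0.42 for fatty acid oxidation and −0.27 for oxidative phosphorylation. Only the oxidative phosphorylation call was lost of these 3 (camera adjusted p = 0.0881), but 7 of the 8 genes of the marker list mark urothelium. With Slc14a2, its one medullary gene, the medians were 0.05, −0.06 and 0.28 and the 3 calls were lost. A single gene that itself ran higher in db/db (2.26, SE 1.16) cannot separate medulla tissue from genotype. Without db/db 2, db/db 3 and db/m 2 the S1-S2 median was −0.32 and its call was lost, with a smaller fold and 5 libraries. It was −0.70 (camera adjusted p = 0.0031) in the 4 of these 5 with mitochondrial shares under 40%, which leave out db/m 1, so whether the 3 libraries carry part of the difference stays open. A wrong label of db/db 4 stays open as well: of 181 genes called without it, db/db 4 lay nearer the other db/db libraries at 35.9%, and each db/m library, held out in turn, lay nearer db/db 1 to 3 at 35.4%, 22.1%, 9.39% and 1.66% of as many genes, so the share does not decide. Against a wrong label, all 13 genes called on the 8 libraries were also called without db/db 4, which lay with db/db at each (Slc22a7 at 3.77 CPM against 91.3 to 149), and its male-biased score of −1.47 was below the lowest of db/m (−1.05), but the 13 were chosen with db/db 4 in the db/db group. Milder disease in this animal was not tested.

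Male-biased kidney genes were lower and female-biased ones higher in db/db. Female animals among the db/db mice are argued against, since in 4 of 4 db/db libraries the Y-linked genes exceeded Xist by more than 10 times. A lower share of proximal tubule RNA as the whole cause is argued against too: relative to the S1-S2 list of the same library, male-biased genes were lower (difference −1.69 on the log2 scale) and female-biased genes higher (2.04), each with an exact permutation p of 0.029, the smallest possible, and male-biased genes were also lower relative to the S3 list (−1.02, exact permutation p = 0.029, shared genes left out). Lower androgen signalling in db/db males is a candidate explanation that remains open. With an estimated correlation the male-biased list was not past the threshold (camera adjusted p = 0.861, unadjusted p = 0.063). Directional fry did not call it either (adjusted p = 0.198, unadjusted p = 0.0104), and no hormone measurement was analysed here. With the mitochondrial share as a covariate the median of the male-biased list was −2.05.

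Ugt1a2 had 0 counts in each db/m library and 916 to 28903 in db/db. Its exons from the second on are shared with the other Ugt1a genes, so StringTie's division of reads among members may have produced the contrast. The family sum differed by 0.24 on the log2 scale with a pooled SD of 1.32 (exact permutation p = 0.83), too wide a spread to tell a shift of reads between members from a true rise of Ugt1a2, and these cannot be told apart here. A regulated switch of first exons was not tested.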

How the results depend on the processing

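The covariates, the removals of genes or of 3 libraries, the robust fit and the separate fits by mitochondrial share were chosen after seeing the data. The cause of the changes was not tested, except that fits with fewer libraries have less power by construction. Genes higher numbered 0 to 43 and genes lower 0 to 138 when 1 library was left out. No filter gave 7 higher and 31 lower, DESeq2 155 and 263, the replicate block 39 and 65, the mitochondrial covariate 14 and 57 and the medulla score covariate 6 and 13. With Slc14a2 as the covariate edgeR gave 0 and 0 (843 with an unadjusted p under 0.05). edgeR gave 0 and 0 without the 3 libraries (998 with an unadjusted p under 0.05) and 0 and 0 in the 4 libraries with a mitochondrial share under 40% (1331), and 11 and 15 in the 4 over it. Library size alone gave 3 and 9, of which 8 were among the 13, and 75% of calls were lower against 76.9%. DESeq2 made 62.9% of its calls lower. Lists called ranged from 3 to 13 with 1 library left out. Without the 3 libraries 8 were called, and 8 under and 10 over a 40% share. With the medulla score as a covariate 12 were called and with Slc14a2 13, 7 of the latter among the 13 called without it. With an estimated correlation 0 were called (1 with an unadjusted p under 0.05) and by directional fry 0.

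Whether replicate numbers pair the samples stays open. Correlations of same-numbered deviations were 0.14, 0.33, −0.26 and 0.39. db/db 1 and db/db 2 matched db/m 1 and db/m 2 best, but db/db 3 and db/db 4 matched db/m 2 and db/m 3 best. The replicate block raised edgeR calls from 13 to 104 and unadjusted p-values under 0.05 from 2096 to 2729. With the replicate block 13 lists were called, all of them among the 13 called without it.

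Most reversals of direction were of values near 0. Without single libraries Lepr ranged from −0.55 to 0.23, Ren1 from −1.38 to 0.41, Nphs1 from −0.40 to 0.04, Col4a1 from −0.05 to 0.38 and Fn1 from −0.00 to 0.40. Library size alone turned Lepr to 0.12 and Ren1 to 0.13, voom turned Lepr to 0.07 and the replicate block to 0.03. Removal of the 3 libraries gave 0.22 for Lepr, 0.34 for Ren1 and 0.13 for Nphs1. The test direction of some lists turned without single libraries, over which the median ranged from −0.38 to 0.78 for the mitochondrial genome, −0.34 to 0.17 for podocytes, −1.20 to 0.29 for adipocytes, −1.58 to 1.39 for medulla, −0.35 to 0.14 for the thick ascending limb, −1.07 to 0.07 for gluconeogenesis and −0.69 to 0.08 for PPAR-alpha targets. It ranged from −0.21 to −0.05 for fatty acid synthesis, −0.23 to 0.17 for antioxidant genes, −0.25 to 0.12 for cytokines, −0.55 to 0.19 for interferon genes, −0.28 to 0.08 for clock genes and −0.23 to 0.13 for endoplasmic reticulum stress. With the test direction turned, the mitochondrial genome was at −0.01 with the covariate and −0.59 without the 3 libraries (camera adjusted p = 0.00663), podocytes at −0.07 with the replicate block and cytokines at 0.05 with the stricter filter. Without the 3 libraries injury markers were at 0.07, endothelial genes at −0.07 and intercalated cells at −0.04. Over the named genes and lists and all alternatives, 1572 comparisons kept direction and side of the threshold, 39 passed it newly, 166 lost it in the same direction and 52 turned. Counts outside the dominant genes were fewest in db/db 3 (10048180) and genes with at least 10 counts in db/db 2 (17956).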

Other observations

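Several lists that were not called as a whole held members that differed when adjusted over the list alone. Among 18 PPAR-alpha target and ketone genes (median −0.37, camera adjusted p = 0.605), Cyp4a14 (log2 fold change 3.72) was higher and Cd36 (−2.89), a fatty acid carrier, was lower; without db/db 4 4 were lower. Among 19 genes of glycolysis, polyol and fructose handling (median 0.28, camera adjusted p = 0.183), Pfkp (1.00) and Hk1 (1.04), which act early in glycolysis, were higher. With the DESeq2 size factors or the stricter filter 0 glycolysis genes passed, and with the replicate block 3 were higher. Without db/db 1, db/db 2, db/db 3, db/m 2, db/m 3 or db/m 4, 0 glycolysis genes passed adjusted over the list alone; without db/m 1 6 were higher, and without db/db 4 2 were higher and 1 lower. Among 18 clock genes (median −0.09, camera adjusted p = 0.605), Per2 (−1.36) and Per3 (−1.22) were lower, while Npas2 (1.60) and Arntl (1.21) did not pass; 0 clock genes passed without db/db 1, db/db 2 or db/db 3, and 1 was higher and 4 lower without db/db 4. No clock, glycolysis or renin-angiotensin gene passed over all genes tested by edgeR; 5, 5 and 5 of them had an unadjusted p under 0.05.

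Injury markers of the proximal tubule were mixed (20 genes, median 0.55, camera adjusted p = 0.605). Adjusted over the list alone Lcn2 was higher (15.2 ± 6.63 against 2.51 ± 1.94 CPM, 2.60), and Il34 (−1.75) and Havcr1 (0.042 ± 0.0486 against 0.558 ± 0.258 CPM, −3.46) were lower. Gsta2 (3.97), a glutathione transferase, was higher and Osgin1 (−1.29) lower among 21 antioxidant genes (median −0.08, mean 0.19, test direction up, camera adjusted p = 0.779). Agt (1.18), the angiotensinogen gene, was higher and Mas1 (−2.75) lower among 11 genes of the renin-angiotensin system (median −0.38, camera adjusted p = 0.211), a list that was called without db/db 4 (0.0381, 5 members lower adjusted over the list alone). The smooth muscle genes Tagln (−0.95) and Acta2 (−0.87) were lower among 11 stromal genes (median −0.46, camera adjusted p = 0.135), which were called without db/m 3 (0.0485). Plin4 (1.61) was higher among 10 adipocyte genes (median −0.07, mean −0.45, test direction up, camera adjusted p = 0.635). Without db/db 2, db/db 3, db/db 4, db/m 1, db/m 2 or db/m 4, 0 adipocyte genes passed. For antioxidant genes the number lower was 0 without 6 of the 8 libraries, 3 without db/db 4 and 1 without db/m 3, and the number higher was 3 without db/m 3. For stromal genes the number lower was 0 without db/db 2, db/db 3, db/m 1 or db/m 4 and 1 without db/m 2 or db/m 3. For renin-angiotensin genes the number lower was 0 without db/db 1, db/db 3, db/m 3 or db/m 4, and the number higher was 0 without db/m 3 or db/m 4. For injury genes 1 to 3 were higher and 1 to 3 lower without each library. Without the 3 doubted libraries 0 injury, stromal and renin-angiotensin genes passed adjusted over the list alone.

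With all 8 libraries the remaining lists gave no call and no member past the threshold adjusted over the list alone. Without db/db 4 members passed in several: 3 lower for the thick ascending limb, 3 lower and 1 higher for the distal convoluted and connecting tubule (median −0.46), 4 lower for gluconeogenesis (median −1.07), 3 higher and 3 lower for heat shock, 2 lower for complement, 2 higher for endoplasmic reticulum stress and 1 higher each for podocytes and principal cells, and the intercalated cell median was −0.59. Without db/m 1, 1 thick ascending limb and 1 heat shock gene were higher, and without db/m 4, 1 medulla gene was lower. With all 8 libraries the medians were −0.21 for endothelial genes, −0.00 for the thick ascending limb, −0.24 for the distal convoluted and connecting tubule, 0.08 for principal cells, −0.11 for intercalated cells, −0.44 for gluconeogenesis, −0.07 for fatty acid synthesis and storage, −0.09 for inflammatory cytokines, −0.00 for the interferon response, −0.31 for complement, 0.25 for the cell cycle, −0.09 for endoplasmic reticulum stress and 0.00 for heat shock. The interferon list was called without db/db 3 (median −0.55, camera adjusted p = 0.00262) and complement without db/m 4 (median −0.47, 0.0439). Markers of medulla and urothelium had a median of −1.17, a mean of −0.91 and a test direction of up (camera adjusted p = 0.69), and a median of 0.96 with the replicate block; their score was 3.41 in db/m 1 and −3.82 in db/m 4, the widest spread of any list. The neutrophil list, with 4 tested members, had a median of 0.25.

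One hypothesis set before its result was seen was that DNA of another strain, carried along with the db mutation, may alter genes near Lepr, though the level of 1 gene in that region had been looked at in each library. Within 10 Mb of Lepr 19 of 124 genes (15.3%) had an unadjusted p under 0.05, against 11.2% of 18601 other genes, an odds ratio of 1.44 with a two-sided Fisher's exact p of 0.15. The difference was not past the threshold and the hypothesis stays open.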
